A study of Mus musculus with 18 samples.

How the data were processed

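Heart RNA was measured on 18 single-colour Affymetrix Mouse Genome 430 2.0 arrays, from control mice and mice lacking a working Kir6.1 gene. Per the labels' protocols, hearts were homogenised in Trizol straight after dissection, and total RNA was amplified in a single round and labelled with biotin. The series' design text speaks of 3 mice per genotype and gives an LPS amount of 0.5 µg in PBS. The labels number the hearts 1 to 3 in each group but do not state that every number is a separate animal, so p-values measure only the spread between these arrays, which may be partly technical.

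The deposited values are on the log2 scale and, per the submitters' processing notes, come from RMA, the robust multi-array average that corrects background, normalizes between arrays and summarises the probes of a probe set. Its version, settings and any later scaling are not given in the sources used here. The array medians of the deposited log2 values ran from 4.71 to 4.97, so the columns did not share 1 distribution, and the values ran from 2.67 to 14.4. RMA compresses small signals towards a floor, so differences of dim probe sets are understated. Other fields used are the text fields of each array's own experiment file, deposited beside the values, which give the hybridization day, array lot and fluidics protocol and hold no measurement. The precision of the comparisons is limited by the number of arrays.

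Of 45101 probe sets, 64 Affymetrix controls were left out and 45037 were tested. The platform annotation gave 1 gene symbol for 34945 of the tested probe sets, several for 932 and none for 9160. Entrez identifiers of 34754 matched the gene table, and 0 symbols needed an update. A gene was represented by the probe set with the highest mean over all arrays, which gave 18193 genes, and probe sets with several symbols named no gene. No value column belonged to a sample outside the 18 arrays.

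The group comparisons used limma 3.58.1 in R 4.3.3. A model of 6 group means was fitted to all 18 arrays with 12 residual degrees of freedom, and eBayes added 3.83 prior degrees of freedom. Contrasts gave the LPS effect within each genotype, the genotype effect within each condition, the genotype effect averaged over the 3 conditions, the differences of LPS effects between genotypes, and LPS 3 h against LPS 30 min. Within each contrast, Benjamini-Hochberg adjustment was used with a threshold of 0.05. Errors beside log2 changes are standard errors of the fit unless stated otherwise, and errors beside group levels are standard deviations over 3 arrays. The Kcnj8 difference was also tested by a two-sided exact permutation of the genotype within conditions.

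There were 36 lists of genes for pathways and for cell types that a heart sample could hold, with 548 genes, of whose 553 entries 507 had a probe set. The lists were tested with limma's camera at its preset correlation of 0.01 between genes, on 1 probe set per gene, with adjustment over the lists within a contrast. Beside it stand the count of members past the threshold over all probe sets, the count adjusted over the list alone, camera with an estimated correlation, and fry. Of 114 camera calls among 396 pairs of list and contrast, 13 also passed with an estimated correlation and 61 also passed by fry. The 13 include the K-ATP channel list for the genotype after PBS, at 30 min and over the conditions (camera adjusted p = 0.0112, 0.00229 and 0.0357). Its 4 members include Kcnj8, the gene disrupted in the mutants, so these calls were fixed in advance. The only other genotype calls among the 13 were MHC class I after PBS and smooth muscle and pericytes at 30 min. The preset correlation treats list members as nearly independent, so those adjusted p-values are small compared with the others.

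Genes were named by a rule. It takes the 4 subunits of the K-ATP channel. It adds up to 10 genes each way with the largest log2 change among those past the threshold, whose arrays did not overlap between the groups compared and whose higher group mean was at or above the median of all probe sets, 4.85. For differences of effects and averaged contrasts the overlap condition was dropped, and symbols that are only clone or model names were left out. From each list described, it adds up to 4 members past the threshold, or the 2 with the smallest p-value where none passed. Genes named outside the rule are said to be chosen after their values were seen. The grouping, the tests, the lists, the naming rule and most of the other settings were fixed before the data were examined.

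The experiment files showed 3 hybridization days. All PBS arrays, all control LPS 3 h arrays and mutant LPS 3 h replicate 2 were hybridized on the first day, mutant LPS 3 h replicates 1 and 3 on the second, and all LPS 30 min arrays on the third. Within-day fits used first-day arrays with 6 residual degrees of freedom, or third-day arrays with 4. In the first-day fit the lone mutant LPS 3 h array is assumed to vary like the other groups. The 3 mutant LPS 3 h arrays correlated least with their own group, at 0.9535 to 0.9633 against at least 0.9844 elsewhere. First-day p-values for that group may therefore be too small. The fit to all arrays also shares 1 spread over groups that differ in spread. Array weights, which are lower for arrays with more spread, were 0.115 to 0.294 on mutant LPS 3 h arrays. They were 0.302, 0.361 and 2.35 on control LPS 3 h arrays and 0.965 to 2.76 elsewhere. All-array p-values of contrasts with LPS 3 h arrays may thus be too small, and those among the other groups too large. The contrasts of LPS 30 min with PBS or with LPS 3 h have no array of both groups on 1 day, so for them hybridization day and treatment time cannot be told apart, and day was entered as a random block.

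The other settings fixed at that point were a filter at the median level, quantile normalization, centring on the median, an intensity trend with a robust prior, only the arrays of the groups compared, the replicate number as a block, array weights, a log2 change of at least 1, the difference of 3' and 5' control probe sets as a covariate, hybridization day as a block, leaving out each array, the mean of all probe sets of a gene, and other list tests. Fits without the 2 arrays of the second day and within single days were chosen after seeing the data. A covariate for sex was planned for the case that arrays differed in it, and they did not.

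The fit was tested on simulated data for 45037 probe sets with 50 changed at each of 4 sizes. The noise was independent and normal, with the same spread in every group and no shift between days. Only probe sets at or above the median level were changed. The real arrays differ in spread and day, so the shares and false calls below need not hold for them. For the LPS effect at 3 h in control hearts it recovered 24% of changes of 0.5 log2, 76% of 1, 98% of 2 and 98% of 3, with 11 false calls. For mutant against control after PBS the shares were 24%, 78%, 98% and 100%, with 8 false calls. A second run took the spread of the groups other than mutant LPS 3 h and left out the second-day arrays. It recovered 60%, 94%, 100% and 100% for LPS 3 h in controls. For the genotype after PBS it recovered 38%, 92%, 100% and 100%, with 9 false calls in each comparison.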

Results

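Expression was measured in the hearts of control mice and of mutants deficient in Kir6.1, the pore-forming subunit of the ATP-sensitive potassium (K-ATP) channel of vascular smooth muscle, encoded by Kcnj8. Mice received lipopolysaccharide (LPS), the bacterial endotoxin that activates Toll-like receptor 4, at 0.5 µg in PBS, or PBS alone. Hearts were taken 3 h after PBS, 30 min after LPS or 3 h after LPS, with 3 arrays for each genotype and condition. The comparisons ask how the mutant heart differs from the control heart and how each responds to LPS. Values are log2 RMA signals as deposited, and changes are log2 differences.

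The arrays did not all have the same RNA quality signal. The 3' minus 5' signal of the Gapdh and Actb control probe sets, which rises with degraded or shortened RNA, was 1.37 on mutant LPS 3 h replicate 1 and 1.09 on replicate 3, against 0.13 to 0.44 on the other 16 arrays. Those were also the only arrays hybridized on the second day, and they lay at 83.4 and 132 on the first principal component, which held 46.9% of the variance. The remaining mutant LPS 3 h array, replicate 2, was hybridized with the PBS and control LPS 3 h arrays. It came from a different array lot than these, and PBS and control LPS 3 h arrays also differed in lot. Array lot and group therefore cannot be told apart in the first-day comparisons that involve LPS. The closest pair of arrays still differed with a standard deviation of 0.16, and no array was a copy of another.

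**Figure D1:**
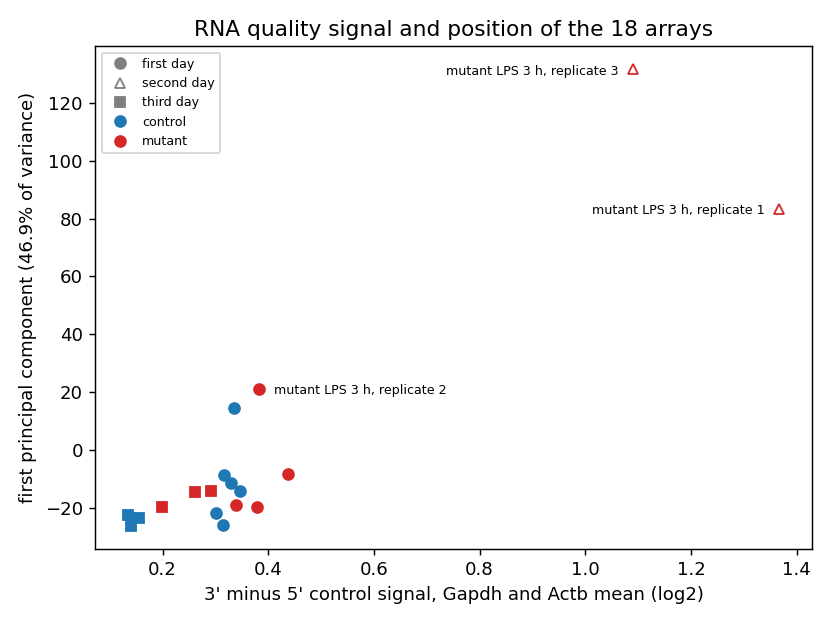
The 3' minus 5' control signal (log2, horizontal) is plotted against the first principal component (vertical) for each of the 18 arrays, with marker shape for hybridization day and blue for control, red for mutant. The 2 open triangles, mutant LPS 3 h replicates 1 and 3, stand apart at 1.37 and 1.09.

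Kcnj8 was low on every mutant array, at 4.35 to 5.36, and high on every control array, at 8.35 to 8.90. After PBS the mean was 8.60 ± 0.09 in controls and 4.50 ± 0.20 in mutants (SD, n = 3 each), a difference of -4.10 (SE 0.15). The difference was -3.96 at 30 min and -3.34 at 3 h after LPS, and -3.80 over the 3 conditions (SE 0.085, limma adjusted p = 1.84e-13). The exact permutation p over 8000 regroupings was 0.00025, the smallest they can give. Where the probes lie relative to the mutation was not examined here. In mutants Kcnj8 was 0.81 higher 3 h after LPS than after PBS (adjusted p = 0.00295), close to the median of all probe sets, 4.85. On the first day alone that change was 0.77 (adjusted p = 0.0613). The other channel subunits, Kcnj11 (Kir6.2), Abcc8 (SUR1) and Abcc9 (SUR2), differed between genotypes by -0.17, -0.10 and -0.09 over the conditions and did not pass (adjusted p = 0.147, 0.342 and 0.379). Adjusted over the list of 4 subunits alone, Kcnj11 was also lower (adjusted p = 0.0285).

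**Figure D2:**
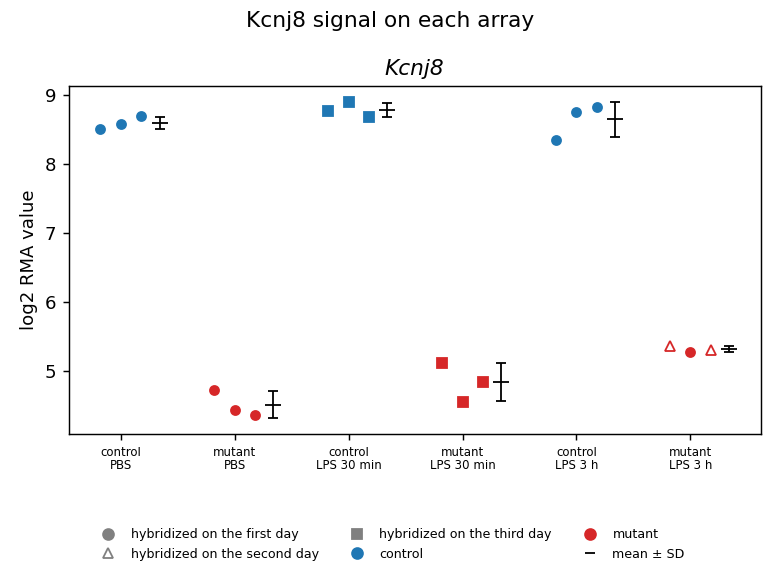
Kcnj8 (log2 RMA value, vertical) on each array of the 6 groups, with bars for mean ± SD of 3 arrays, marker shape for hybridization day and blue for control, red for mutant. All mutant arrays lie at or below 5.36 and all control arrays at or above 8.35.

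In control hearts, LPS raised the adhesion molecule genes Selp, Icam1 and Vcam1, several interferon-induced genes and single chemokine genes by 3 h. Selp and Icam1, endothelial receptors that capture leukocytes, rose by 3.89 (SE 0.76, 14.8-fold) and 3.32 (SE 0.46, 9.99-fold), and Vcam1 by 2.73. Icam1 went from 7.19 ± 0.11 to 10.5 ± 1.44 (SD, n = 3 each). The other leading genes were Ccl12, a monocyte attractant, Serpina3n, an acute-phase protease inhibitor, Casp4, the caspase that senses LPS in the cytosol, Pfkfb3, an activator of glycolysis, and the interferon-induced Ifit1, Ifi47 and Ifit2, at 2.29 to 3.21. Nppb, which encodes the natriuretic peptide BNP, fell by 1.04 (adjusted p = 0.00932). Fgd5, Adam19, Dmtn, Fam102a, Ppp1r16b, Rbx1, Fzd7, Zfp712 and Eepd1 also fell, by -0.67 to -1.04.

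By group, the interferon response had the most risen members in control hearts, and MHC class I the largest share of members risen. Of 30 measured members 14 rose, 0 fell and 16 did not pass, and 26 rose adjusted over the list alone (camera adjusted p = 4.34e-36, and adjusted p = 0.0297 with an estimated correlation). Of 12 genes of MHC class I antigen presentation 6 rose and 0 fell, among them the peptide transporter genes Tap1 (1.43) and Tap2 (0.94) and the immunoproteasome genes Psmb9 (1.23) and Psmb8 (1.06). Adjusted over the list alone 11 rose (camera adjusted p = 3.26e-20, and adjusted p = 0.000278 with an estimated correlation). Of 18 genes of the NF-kB pathway and its feedback inhibitors 5 rose, including Relb (1.72), Bcl3 (1.68), Birc3 (1.54) and Nfkb2 (1.06), 13 did not pass, and 9 rose adjusted over the list alone (camera adjusted p = 7.65e-14, and adjusted p = 0.0343 with an estimated correlation). STAT3 targets and acute phase genes had 5 of 21 risen and 0 fallen, with Mt2 at 1.86 and Osmr at 1.31, and 10 risen adjusted over the list alone (adjusted p = 8.99e-15, and adjusted p = 0.0158 with an estimated correlation). Glucocorticoid-responsive genes had 4 of 15 risen and 0 fallen, among them Fkbp5 (1.52) and Cebpd (1.37), and 8 risen adjusted over the list alone (adjusted p = 4.18e-12, and adjusted p = 0.0203 with an estimated correlation).

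Other lists had fewer members past the threshold in control hearts. Chemokines had 3 of 20 risen, Ccl12, Cxcl9 (2.25) and Ccl9 (1.23), 0 fallen, and 9 risen adjusted over the list alone (camera adjusted p = 2.06e-09, but adjusted p = 0.111 with an estimated correlation). Endothelial activation genes had 3 of 13 risen, Selp, Icam1 and Vcam1, 0 fallen, and adjusted over the list alone 5 risen and 1 fallen (adjusted p = 0.000611, but adjusted p = 0.112 with an estimated correlation). Of 16 monocyte and macrophage markers 2 rose, Fcgr3 (0.91) and Mrc1 (0.79), 0 fell, and 7 rose adjusted over the list alone (adjusted p = 7.64e-08, and adjusted p = 0.0297 with an estimated correlation). Of 17 apoptosis and survival genes 2 rose, Casp4 and Fas (1.12), 0 fell, and 5 rose adjusted over the list alone (adjusted p = 2.90e-06, and adjusted p = 0.0277 with an estimated correlation). Of 15 genes of the Toll-like receptor pathway 1 rose, Lbp (0.97), 0 fell, and 7 rose adjusted over the list alone (adjusted p = 0.000214, but adjusted p = 0.125 with an estimated correlation). None of 13 neutrophil markers passed over all probe sets and 3 rose adjusted over the list alone (adjusted p = 7.61e-05, and adjusted p = 0.0345 with an estimated correlation). None of 18 cytokine genes passed over all probe sets and 1 rose adjusted over the list alone, with Csf1 at 0.93 (adjusted p = 0.12) and Tnf at 0.41 (adjusted p = 0.309). Of 25 immediate early genes, the transcription factors and regulators first switched on by stimuli, 0 rose and 1 fell, Klf4 at -0.66, and adjusted over the list alone 2 rose and 1 fell, with a list median of 0.01 and a test of the opposite sign (adjusted p = 0.974).

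The LPS effect at 3 h in control hearts took 163 probe sets up and 62 down past the threshold, or 116 and 25 genes. Risen probe sets were 72.4% of the calls, 90.6% with each array centred on its median and 61.2% with first-day arrays, but 47.1% without the second-day arrays and 43.3% with array weights. The first-day arrays alone gave 183 calls and day as a block 691. Among the lists above, only MHC class I kept its call on the first day with an estimated correlation (adjusted p = 0.0379). Without control PBS replicate 1, 2 or 3 the count was 79, 33 or 44, and without control LPS 3 h replicate 1, 2 or 3 it was 77, 85 or 611. With only the arrays compared, which have fewer degrees of freedom, far fewer probe sets were called, as given below. The interferon list median was 0.54 above control PBS on LPS replicate 3, against 2.06 and 1.11 on replicates 1 and 2.

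**Figure D3:**
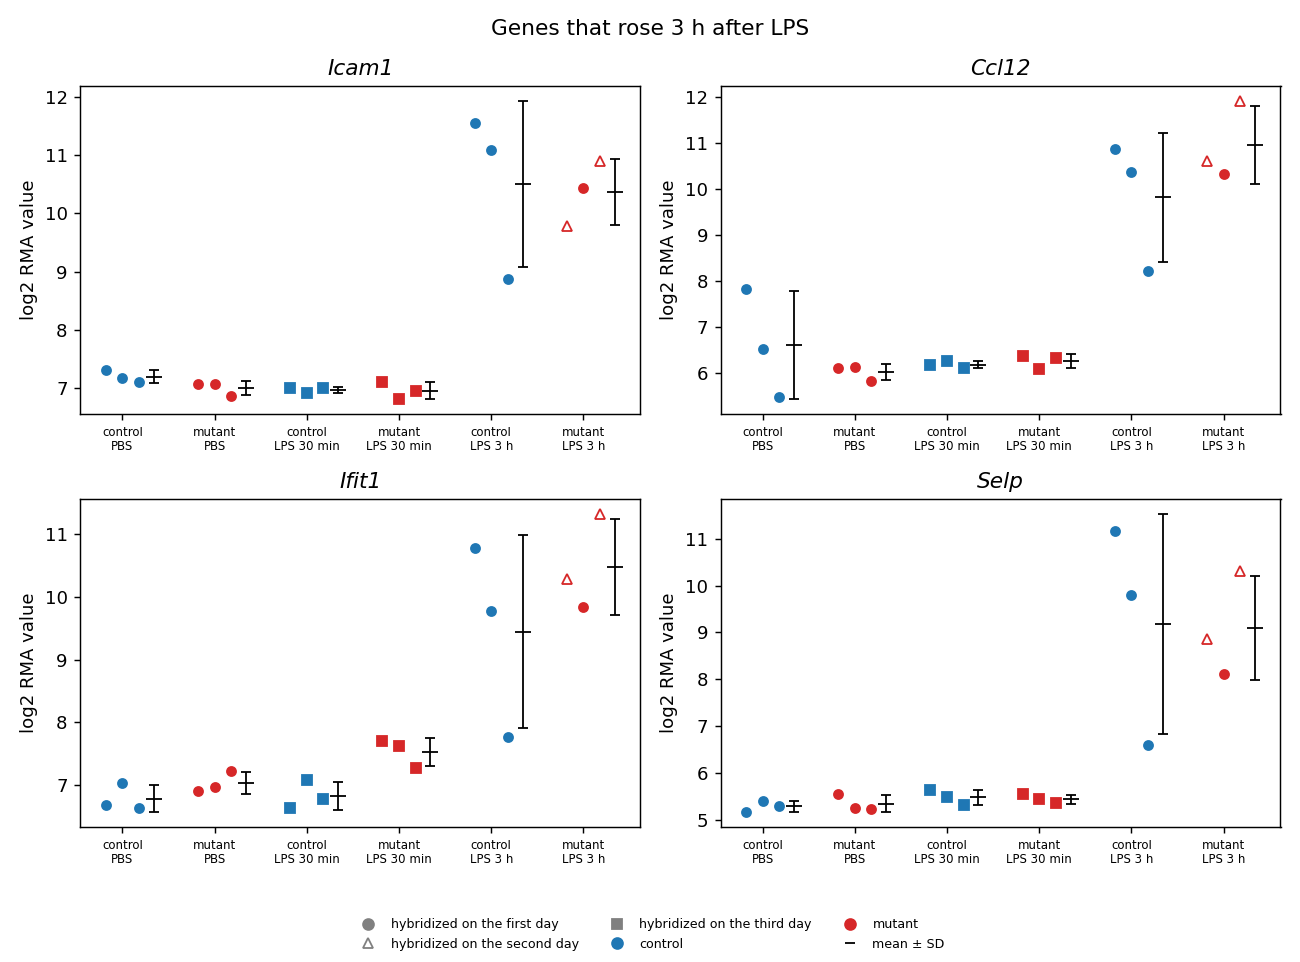
Icam1, Ccl12, Ifit1 and Selp (log2 RMA value, vertical) on each array of the 6 groups, with bars for mean ± SD of 3 arrays, marker shape for hybridization day and blue for control, red for mutant. In each panel the LPS 3 h groups have the highest means, with wide spread among the control LPS 3 h arrays, as for Icam1 at 10.5 ± 1.44.

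In mutant hearts 3 h after LPS, many of the same inflammatory genes were high. Ccl12 rose by 4.93 (30.5-fold, adjusted p = 0.000263), Selp by 3.75, Ifit1 by 3.44 and Icam1 by 3.38. Mt2, a metal-binding protein of the acute phase, rose by 3.24, the neutrophil alarmins S100a9 and S100a8 by 3.15 and 3.09, and the siderophore-binding Lcn2 by 3.05. Slc10a6 and Pfkfb3 completed the leading 10. Of the 116 genes that rose in controls, 89 also rose in mutants, against 11.5 for independent lists, and 10 of the 25 that fell also fell, against 4.03. On the first day alone 28 of 76 risen genes were shared, against 1.55.

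Among groups, STAT3 targets and acute phase genes had 13 of 21 risen and 0 fallen, with Socs3 at 2.76 and the iron hormone gene Hamp at 2.47, and adjusted over the list alone 14 risen and 1 fallen (camera adjusted p = 5.39e-07, but adjusted p = 0.165 with an estimated correlation). The interferon response had 18 of 30 risen and 0 fallen (20 adjusted over the list alone, adjusted p = 3.48e-07, but adjusted p = 0.374 with an estimated correlation). Chemokines had 9 of 20 risen and 0 fallen, with Ccl7 at 2.79 and Ccl2 at 2.51 (12 adjusted over the list alone, adjusted p = 2.61e-05, but adjusted p = 0.302 with an estimated correlation). The NF-kB list had 9 of 18 risen and 0 fallen, and adjusted over the list alone 13 risen and 1 fallen (adjusted p = 2.23e-05, but adjusted p = 0.259 with an estimated correlation). Glucocorticoid-responsive genes had 9 of 15 risen and 1 fallen, the same adjusted over the list alone (adjusted p = 2.23e-05, but adjusted p = 0.170 with an estimated correlation). Cytokines had 5 of 18 risen and 1 fallen, with Il6 at 1.15 and Il1b at 0.77, and 6 risen and 1 fallen adjusted over the list alone (adjusted p = 0.00921, but adjusted p = 0.205 with an estimated correlation). Immediate early genes had 11 of 25 risen, led by Atf3 (2.86), Fos (2.68), Nr4a1 (2.34) and Egr1 (2.19), and 1 fallen, Klf6, with 13 risen and 1 fallen adjusted over the list alone (adjusted p = 1.98e-06, but adjusted p = 0.165 with an estimated correlation). The group holds the 2 arrays with high 3' minus 5' signal, and with first-day arrays, where replicate 2 is the only mutant LPS 3 h array, 2 interferon response, 2 chemokine, 2 NF-kB, 1 cytokine, 6 STAT3 and acute phase, 8 glucocorticoid-responsive and 14 immediate early genes had risen.

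Metabolic and endothelial groups were lower in mutants 3 h after LPS, in a group that holds both arrays with high 3' minus 5' signal. Of 24 oxidative phosphorylation genes 11 fell and 0 rose, with the complex II genes Sdhd at -0.78 and Sdhc at -0.71, and 15 fell adjusted over the list alone (camera adjusted p = 0.000415, but adjusted p = 0.205 with an estimated correlation). Without the 2 second-day arrays, a choice made after seeing the data, the camera adjusted p was 0.0979. Of 23 fatty acid oxidation genes 6 fell and 0 rose, led by the fatty acid transporter gene Cd36 at -1.23, and 11 fell adjusted over the list alone (adjusted p = 0.000592, but adjusted p = 0.360 with an estimated correlation), and without the second-day arrays the camera adjusted p was 0.475. Of 12 endothelial markers 6 fell and 0 rose, led by Pecam1 at -1.56 and Kdr at -1.18, and 6 fell adjusted over the list alone (adjusted p = 0.00921, but adjusted p = 0.340 with an estimated correlation), and without the second-day arrays the camera adjusted p was 0.115. Cd36 and Pecam1 were then at -0.32 and 0.08. Of 12 cardiomyocyte markers 2 fell, Ttn (-0.90) and Ckm (-0.38), 0 rose, and 4 fell adjusted over the list alone (adjusted p = 0.00921, but adjusted p = 0.165 with an estimated correlation), and without the second-day arrays the camera adjusted p was 0.0379.

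Single genes also fell in mutants, and most named ones lost their call on the first day alone. Cldnd1 fell by 3.01 and Fcho2, a factor of clathrin-mediated uptake, by 2.80, and on the first day alone they were at -2.60 and -1.60. The platelet chemokine Ppbp, Sp3, Smndc1, Zkscan3, Leprotl1, Nup153, Zfp770 and Pcmtd2 fell by -2.08 to -2.77 with all arrays, and none passed on the first day alone. Leprotl1, for example, was then at -0.10. That fit holds 1 mutant LPS 3 h array, so a lost call alone does not show that a gene rests on the second-day arrays. The LPS effect at 3 h in mutant hearts took 3600 probe sets up and 5922 down (1802 and 2932 genes), against 1816 called on the first day alone and 2107 with day as a block. Risen probe sets were 37.8% of the calls, 48.1% after quantile normalization, 26.3% after centring and 48.5% with first-day arrays, but 51 of 66 with only the arrays compared. Without mutant PBS replicate 1, 2 or 3 the count was 6006, 4301 or 4341, and without mutant LPS 3 h replicate 2 or 3 it was 14773 or 3222. The count of 14773 comes from a fit whose only mutant LPS 3 h arrays are the second-day ones.

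The genotype difference in the LPS effect at 3 h was tested directly. Atf3, Nr4a1 and Egr1, stress- and stimulus-induced transcription factors, had LPS effects 2.74, 2.71 and 2.42 higher in mutants than in controls (limma adjusted p = 0.00334, 0.00025 and 0.00334). With first-day arrays, which hold 1 mutant LPS 3 h array, those differences were 2.99, 2.34 and 2.67. Mt3, Fam107a, Errfi1, Arid5a, Ccn1, Izumo4 and Adamts1 were higher by 0.99 to 1.75. Lratd2, Abca5, Orc5, Rsrc1, Dact1, Nars2, Maip1, Acp2, Det1 and Slc49a4 were lower, at -0.64 to -1.44. The genes from Mt3 to Slc49a4 lost their call on the first day alone, in a fit with 1 mutant LPS 3 h array. A lost call there does not show that a gene rests on the second-day arrays.

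Immediate early genes were the group with the clearest difference of LPS effects. Of 25 members 4 were higher, Atf3, Nr4a1, Egr1 and Ccn1, 0 were lower and 21 did not pass, and adjusted over the list alone 13 were higher and 1 lower (list median 0.58, camera adjusted p = 3.69e-06, but adjusted p = 0.333 with an estimated correlation). With first-day arrays, which hold 1 mutant LPS 3 h array, the list median was 0.91. Fatty acid oxidation (adjusted p = 0.000318, but adjusted p = 0.618 with an estimated correlation), oxidative phosphorylation (0.0145 and 0.618), MHC class I (0.00601 and 0.333) and fibroblast markers (0.0221 and 0.678) had lower medians in the difference, with no member past the threshold over all probe sets. Adjusted over the list alone 2 fibroblast markers were lower and no member of the other 3 lists passed. Mutants had the MHC class I list higher than controls after PBS (median 0.27). At 3 h after LPS its genotype median was -0.01, with 2 of 12 members lower (camera adjusted p = 0.505). For fibroblast markers the genotype medians were 0.27 after PBS and 0.05 at 3 h, with 4 of 12 lower (camera adjusted p = 0.37). In both lists the PBS level therefore enters the difference. Without the second-day arrays, which had the high 3' minus 5' signal, the camera adjusted p was 0.277 for fatty acid oxidation, 0.612 for oxidative phosphorylation and 0.0719 for fibroblast markers, and 0.00128 for MHC class I. The genotype difference in the LPS effect at 3 h passed for 25 probe sets as higher and 22 as lower (18 and 11 genes). With day as a block 82 were higher and 22 lower. The first-day fit and the fit without the second-day arrays compare the same arrays here, with 1 mutant LPS 3 h array. The first kept few of those 47 calls and the second most of them. Calls lost on the first day therefore do not show dependence on the second-day arrays. The share that was higher was 53.2%, and 72.3% after quantile normalization, while centring gave 14 higher and 56 lower and array weights 1750 and 4199. The lowest weight of all arrays, 0.115, fell on mutant LPS 3 h replicate 2, against 0.253 and 0.294 on the second-day arrays. Within that group the weighted fit therefore leans on the arrays with high 3' minus 5' signal. Without control PBS replicate 1, 2 or 3 the count was 9, 9 or 10, without mutant PBS replicate 1, 2 or 3 it was 14, 8 or 8, without control LPS 3 h replicate 1, 2 or 3 it was 20, 629 or 19, and without mutant LPS 3 h replicate 1, 2 or 3 it was 936, 10621 or 16. The count of 10621 comes from a fit whose only mutant LPS 3 h arrays are the second-day ones. Far fewer than 47 were called with only the arrays compared, as given below.

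**Figure D4:**
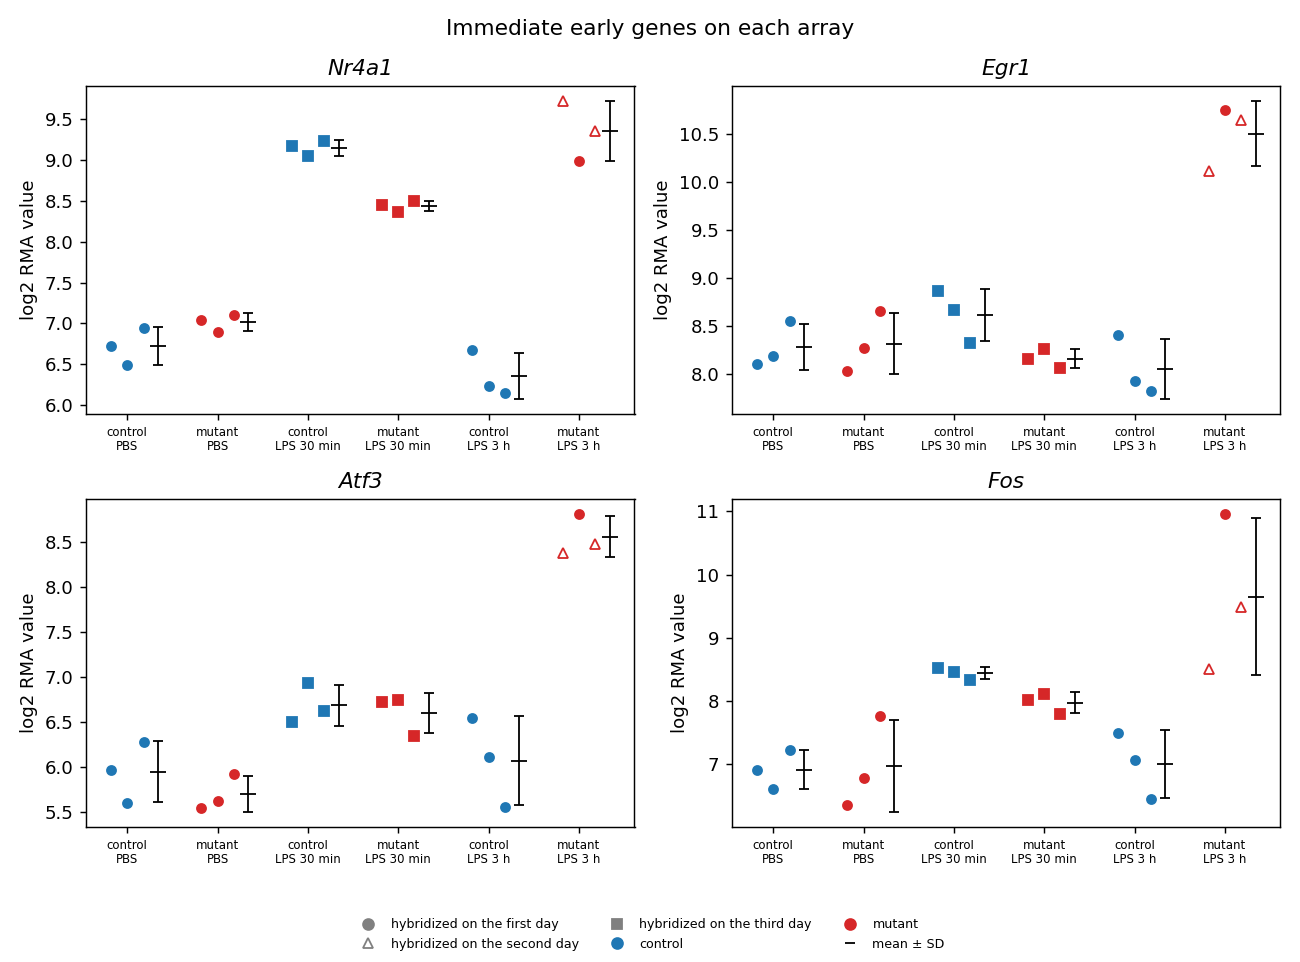
Nr4a1, Egr1, Atf3 and Fos (log2 RMA value, vertical) on each array of the 6 groups, with bars for mean ± SD of 3 arrays, marker shape for hybridization day and blue for control, red for mutant. In the mutant LPS 3 h group the first-day array and both second-day arrays lie above all control LPS 3 h arrays, as for Nr4a1 at 9.36 ± 0.37 against 6.35 ± 0.28.

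Compared directly 3 h after LPS, mutant hearts had higher immediate early genes than control hearts. The p-values of this comparison use a spread shared with less variable groups and may be too small. Nr4a1 was 3.00 higher (adjusted p = 1.66e-07), Fos 2.64, Atf3 2.48 and Egr1 2.45. Of 25 members 13 were higher and 1, Klf6 at -1.94, was lower, and 16 and 1 adjusted over the list alone (camera adjusted p = 3.59e-06, but adjusted p = 0.261 with an estimated correlation). Among first-day arrays, with replicate 2 as the only mutant LPS 3 h array, the list median was 1.14. Nppb was at 12.4 ± 0.26 in mutants and 11.1 ± 0.15 in controls (SD, n = 3 each), a difference of 1.36 (adjusted p = 0.000683). Of the 9 cardiac stress genes 3 were higher and 1, Ankrd1 at -0.83, was lower, and 4 and 1 adjusted over the list alone (camera adjusted p = 0.336, but fry adjusted p = 0.0084). Nmrk2, which makes a precursor of NAD from nicotinamide riboside and is known from stressed muscle, was 3.52 higher (adjusted p = 0.00139), and 2.49 higher on the first day alone, with 1 mutant array.

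Single markers of lung and fat were higher in the same mutant group, and their lists were called by fry (adjusted p = 0.0155 and 0.000582) but not by camera. Of 8 lung markers 2 were higher, the airway secretoglobins Scgb1a1 (3.64) and Scgb3a2 (2.94), and 3 adjusted over the list alone (camera adjusted p = 0.0515, and adjusted p = 0.642 with an estimated correlation), and a further secretoglobin, Scgb3a1, was 2.62 higher. Scgb1a1 read 9.90 and 8.80 on mutant replicates 2 and 3 but 3.66 on replicate 1, within the 3.56 to 3.94 of the other arrays. Of 8 adipocyte markers 3 were higher, Adipoq (2.12), Retn (1.56) and Cidea (0.66), also adjusted over the list alone (camera adjusted p = 0.0515, and adjusted p = 0.308 with an estimated correlation). Without the second-day arrays the camera adjusted p was 6.29e-06 for lung and 0.00111 for adipocyte markers, with replicate 2 as the only mutant array. Higd1b, a pericyte gene, and the chemokine Ccl8 were 1.88 and 1.80 higher, and 0.74 and 0.52 on the first day alone (adjusted p = 0.0673 and 0.168).

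The energy metabolism groups were lower in mutants than in controls 3 h after LPS, again with the high 3' minus 5' signal of the second-day arrays in the mutant group. Of 24 oxidative phosphorylation genes 13 were lower and 0 higher, and 14 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000235, but adjusted p = 0.308 with an estimated correlation). Of 23 fatty acid oxidation genes 8 were lower and 0 higher, led by Cd36 (-1.14) and Acadm (-0.87), and 12 were lower adjusted over the list alone (adjusted p = 0.000134, but adjusted p = 0.486 with an estimated correlation). Without the second-day arrays the camera adjusted p was 0.113 for oxidative phosphorylation and 0.248 for fatty acid oxidation. Apart from Kcnj8, the genes lowest in mutants were Cldnd1 (-3.09, and -2.68 on the first day) and Tmed7 (-2.73, and -0.12 on the first day), where the first day holds 1 mutant LPS 3 h array. Sp3, Fyttd1, Serinc1, Pcp4l1, Pnisr, Aspn and Il13ra1 were at -2.24 to -2.52 with all arrays and at -0.17 to -0.44 on the first day, where none passed. In mutant against control 3 h after LPS, 3588 probe sets were higher and 4721 lower (1774 and 2408 genes), against 423 called on the first day and 609 with day as a block, and which direction had more calls depended on the setting. The share that was higher was 43.2%, and 21.8% after centring, but 72.1% with first-day arrays, 71.9% with day as a block, 69.5% with the 3' minus 5' covariate and 64.9% without the second-day arrays. Without control LPS 3 h replicate 1 or 3 the count was 2463 or 5283, and without mutant LPS 3 h replicate 2 or 3 it was 14775 or 1688. The count of 14775 comes from a fit whose only mutant LPS 3 h arrays are the second-day ones. With only the arrays compared far fewer were called, as given below.

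After PBS, 2 genes besides Kcnj8 passed between the genotypes. Fxyd6, a regulator of the sodium pump, was 0.98 higher in mutants (SE 0.13, n = 3 each, adjusted p = 0.0198) and Ano10, of the anoctamin family of channels and scramblases, was at -1.66 (adjusted p = 0.00685). Of 12 MHC class I genes none passed over all probe sets, 5 were higher adjusted over the list alone, and the list median was 0.27 (camera adjusted p = 1.28e-06, and adjusted p = 0.0216 with an estimated correlation). In the fit of first-day arrays, which hold all PBS arrays, the adjusted p with an estimated correlation was 0.267. Of 12 endothelial markers none passed and 2 were higher adjusted over the list alone, with Tie1 at 0.72 and Cdh5 at 0.61 (adjusted p = 0.000212, but adjusted p = 0.203 with an estimated correlation). Of 12 smooth muscle and pericyte markers none passed and 1 was higher adjusted over the list alone (adjusted p = 0.0439, but adjusted p = 0.203 with an estimated correlation). Fibroblast markers had 4 of 12 higher adjusted over the list alone (adjusted p = 0.00131, but adjusted p = 0.334 with an estimated correlation), and platelet markers 1 of 8 (adjusted p = 0.00111, but adjusted p = 0.334 with an estimated correlation), with Ppbp at 2.31 (adjusted p = 0.518). Both of these lists had 0 members past the threshold over all probe sets. Interferon response genes were higher as a list (median 0.27, camera adjusted p = 0.00102, but adjusted p = 0.576 with an estimated correlation), with no member past the threshold. Glucocorticoid-responsive genes were lower (median -0.12, adjusted p = 0.00596, but adjusted p = 0.334 with an estimated correlation), with 1 higher and 2 lower adjusted over the list alone. In mutant against control after PBS, 2 probe sets were higher and 2 lower, while the fit of first-day arrays called 4 and 5, and day as a block 40 and 8. A fit to only the PBS arrays called many more, as given below, so the few calls here do not show a small genotype effect. Without control PBS replicate 1, 2 or 3 the count was 2, 1 or 1, and without mutant PBS replicate 1 or 2 it was 1 or 2.

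At 30 min after LPS, the genes past the threshold between the genotypes were Kcnj8, Pfkp, a glycolytic phosphofructokinase, 0.63 higher in mutants, and Cep128, a centriole protein, at -0.90 (adjusted p = 0.0395 for both). Mural markers had a list median of 0.28 over 12 genes, with 0 past the threshold over all probe sets or adjusted over the list alone (camera adjusted p = 0.000437, and adjusted p = 0.023 with an estimated correlation). In the fit of third-day arrays alone, which hold both groups, the adjusted p with an estimated correlation was 0.294. Vtn and Rgs5, both pericyte genes, were at 0.52 and 0.32. Endothelial markers (list median 0.23, adjusted p = 0.000152, but adjusted p = 0.162 with an estimated correlation) and interferon response genes (0.35, adjusted p = 3.03e-06, but adjusted p = 0.413 with an estimated correlation) had no member past the threshold, also adjusted over the list alone. With third-day arrays alone 5 of 30 interferon response genes, 1 endothelial and 2 mural markers were higher. The interferon list was already higher in mutants after PBS, with a median of 0.27. The genotype difference in its 30 min effect had a median of 0.02 (camera adjusted p = 0.598). Glucocorticoid-responsive genes had 3 of 15 higher adjusted over the list alone and 0 over all probe sets (adjusted p = 3.03e-06, but adjusted p = 0.156 with an estimated correlation). In mutant against control 30 min after LPS, 2 probe sets were higher and 2 lower. The fit on the third day alone, which holds all 6 arrays, called 675 and the fit with day as a block 46. The share that was higher was 50%, 25% after quantile normalization and 66.7% after centring. Without control replicate 1, 2 or 3 the count was 1, 1 or 2, and without mutant replicate 1, 2 or 3 it was 1 each.

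Averaged over the 3 conditions, Nmrk2 was 2.41 higher in mutants (adjusted p = 0.000439), and the pericyte gene Higd1b and the tight junction gene Cldn5 of endothelium were 1.17 and 1.04 higher. Trp53i11, Rbp7, Thy1, Scgb3a1, Ppp1r14a, Ctla2a and Cks2 were 0.91 to 1.17 higher. Scgb3a1 is a secretoglobin like Scgb1a1, and its difference at 3 h is given above. The mean of the lung markers was 1.06 higher at 3 h, against 0.005 after PBS and 0.006 at 30 min. Ano10 was at -1.31, Cldnd1 at -1.49, the mitotic gene Cenpf at -1.20, and Pkd2l2, Ift81, Maob, Gpr22, Myot and Zbtb16 at -0.80 to -1.12. Of 21 vasoactive signalling genes 6 were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.0646). They included the apelin receptor gene Aplnr (0.66), the endothelin receptor gene Ednrb (0.52), the endothelial nitric oxide synthase gene Nos3 (0.48) and, lower, the angiotensin receptor gene Agtr1a (-0.39). Of 9 cardiac stress genes 2 were higher, Nppb (0.65) and Acta1 (0.62), and adjusted over the list alone 4 were higher and 1 lower (adjusted p = 0.0387, but adjusted p = 0.222 with an estimated correlation).

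Immediate early genes had 7 of 25 higher over the conditions and 9 adjusted over the list alone (camera adjusted p = 0.000210, but adjusted p = 0.222 with an estimated correlation). The average came from 3 h after LPS, where the list median was 0.76, against 0.06 after PBS and -0.08 at 30 min. Endothelial markers had 1 of 12 higher, Tie1 (0.49), and 5 adjusted over the list alone (adjusted p = 0.0191, but adjusted p = 0.349 with an estimated correlation), and mural markers 1 of 12, Pdgfrb (0.74), and 5 adjusted over the list alone (adjusted p = 0.0387, but adjusted p = 0.191 with an estimated correlation). Oxidative phosphorylation had 2 of 24 lower and 8 adjusted over the list alone (adjusted p = 3.95e-05, but adjusted p = 0.191 with an estimated correlation), with mean changes of -0.04 after PBS, -0.05 at 30 min and -0.25 at 3 h, where mutants include the arrays with high 3' minus 5' signal. In mutant against control over the 3 conditions, 624 probe sets were higher and 431 lower (421 and 182 genes), and 422 higher and 189 lower with day as a block, but 2563 and 3889 with array weights, and 661 of the 1055 calls remained without the second-day arrays. The genotype changes after PBS and at 30 min after LPS correlated across 12693 genes at r = 0.48 (rho = 0.37), and genes are not independent replicates. Without control PBS replicate 1, 2 or 3 the count was 565, 495 or 466, and without mutant PBS replicate 1 or 2 it was 449 or 618. Without control LPS 30 min replicate 1, 2 or 3 it was 467, 607 or 415, and without mutant LPS 30 min replicate 1, 2 or 3 it was 594, 546 or 538. Without control LPS 3 h replicate 1 it was 664, and without mutant LPS 3 h replicate 2, which leaves only the second-day arrays in that group, it was 8904.

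At 30 min after LPS against PBS, Nr4a1 rose in both genotypes, by 2.43 in controls (adjusted p = 7.93e-06) and 1.42 in mutants (adjusted p = 0.00563). In controls the smooth muscle transcription factor co-activator Myocd fell by 1.47, the glucocorticoid-induced transcription factor Zbtb16 by 2.06, and Malat1, Calr and H3f3a by -0.74 to -1.90, while AY036118, Aldh1l1, Cep128, Cdc42, Apool, Cabcoco1, Ube3a, Ddx6 and Cdc26 rose by 0.41 to 1.02. In mutants the heat shock gene Hspa1b rose by 1.90 (adjusted p = 0.00861), its co-chaperone gene Dnajb1 also rose (adjusted p = 0.0203), and Myocd and H3f3a fell by 1.19 and 0.73. Of 14 heat shock and chaperone genes 2 rose in mutants and 6 adjusted over the list alone (camera adjusted p = 1.86e-08, but adjusted p = 0.055 with an estimated correlation), and in controls 0 rose and 2 adjusted over the list alone (adjusted p = 0.0291, but adjusted p = 0.430 with an estimated correlation). Immediate early genes had 1 of 25 risen in each genotype, with 6 adjusted over the list alone in controls (adjusted p = 1.41e-05, but adjusted p = 0.195 with an estimated correlation) and 4 in mutants (adjusted p = 0.00307, but adjusted p = 0.491 with an estimated correlation). Glucocorticoid-responsive genes had 1 of 15 fallen in controls, Zbtb16, and adjusted over the list alone 6 fallen and 1 risen (adjusted p = 0.000972, but adjusted p = 0.372 with an estimated correlation). In mutants 0 passed, and adjusted over the list alone 3 had risen and 1 fallen, with the list higher (adjusted p = 0.00516, but adjusted p = 0.501 with an estimated correlation).

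The arrays of these 2 conditions were hybridized on different days, so day and treatment time cannot be told apart here. PBS hearts were taken at 3 h only, so LPS and time after injection also differ together. Controls had 20 probe sets risen and 44 fallen, and mutants 5 and 17, against 1 and 0 calls with day as a random block. The risen share in controls was 31.3%, and 45.5% after centring, but 63.7% without the second-day arrays, 59.0% with only the arrays compared and 57.5% with array weights. In mutants it was 22.7%, 33.3% after centring, 40.8% without the second-day arrays and 50% after quantile normalization, and array weights gave 1341 risen and 1286 fallen. In controls, the count without PBS replicate 1, 2 or 3 was 12, 3 or 4, and without LPS 30 min replicate 1, 2 or 3 it was 3, 4 or 11. In mutants it was 7, 10 or 2 without PBS replicate 1, 2 or 3, and 0 or 3 without LPS 30 min replicate 1 or 2. For the difference between the genotypes in this effect limma called 0 probe sets, with 881 at an unadjusted p under 0.05. Glucocorticoid-responsive genes had a median difference of 0.58, with Cebpd and Cdkn1a both at 1.29, and 4 of 15 passed adjusted over the list alone and 0 over all probe sets (camera adjusted p = 1.38e-11, but adjusted p = 0.0575 with an estimated correlation). Mutants had this list lower than controls after PBS (median -0.12) and higher at 30 min (median 0.32), and both enter the difference.

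Between 30 min and 3 h after LPS, with both genotypes averaged, many inflammatory genes were higher at 3 h, but not all. Cytokines had 4 of 18 higher and 1 lower, and the Toll-like receptor pathway 7 of 15 higher and 1 lower. Ccl12 was 4.17 higher, Selp 3.68, Icam1 3.49 and Serpina3n 2.96, and Slc10a6, Lcn2, Mt2, Ifit1, S100a9 and Casp4 were 2.50 to 2.93 higher. Hspa1b was at -1.83, the homeobox gene Meox2 at -1.75, the lymphatic growth factor gene Vegfc at -1.65 and the Notch-induced Nrarp at -1.64, with Fcho2, Aspn, Klhl4, Hhex, Mest and Ccdc69 at -1.46 to -1.75. The interferon response had 21 of 30 higher and 24 adjusted over the list alone (camera adjusted p = 1.99e-11, but adjusted p = 0.273 with an estimated correlation), and chemokines 15 higher and 1 lower of 20, with 16 and 1 adjusted over the list alone (adjusted p = 6.96e-07, but adjusted p = 0.248 with an estimated correlation). The NF-kB list had 13 of 18 higher and 1 lower, the same adjusted over the list alone (adjusted p = 1.95e-07, but adjusted p = 0.185 with an estimated correlation), and neutrophil markers 9 of 13 higher and 11 adjusted over the list alone (adjusted p = 2.22e-05, but adjusted p = 0.0655 with an estimated correlation). Heat shock and chaperone genes had 9 of 14 lower, including Hsp90aa1 (-1.39) and Hspa1a (-1.11), and 10 adjusted over the list alone (adjusted p = 1.11e-05, but adjusted p = 0.0655 with an estimated correlation). In LPS 3 h against LPS 30 min, 4785 probe sets were higher and 6235 lower (2219 and 2812 genes). No day held arrays of both times, and with day as a random block 10 were called. Without control LPS 30 min replicate 3, mutant LPS 30 min replicate 3, control LPS 3 h replicate 2 or mutant LPS 3 h replicate 3 the count was 7129, 7233, 6855 or 6941.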

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

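The tests weighed here were chosen after the results were seen, apart from the counts over other splits of the arrays, which were fixed before; the genotype differences in the LPS effect were planned.

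The 3' minus 5' control signal, which no comparison uses as a measurement, stood at 1.37 and 1.09 on mutant LPS 3 h replicates 1 and 3, above all PBS arrays. These arrays belong to a pattern in which 8309 probe sets differed between mutant and control hearts 3 h after LPS. Over those probe sets the median shift towards the called direction was 0.25 on the first-day mutant array and 0.80 on the second-day arrays, a ratio of 0.311, and 20.5% had a first-day shift of at least 3/4 of the second-day shift. The second-day arrays helped choose these probe sets, and only 1 mutant array lies on the first day, so neither hybridization day or RNA quality nor a genotype difference is excluded, and the 2 cannot be told apart here. Of the 10 splits of these 6 arrays, 2 gave as many calls, with 8353 for the highest other, which sets control replicates 1 and 3 and mutant replicate 2 against control replicate 2 and the second-day arrays, and so, like the real split, holds both second-day arrays on 1 side. On the first day alone 423 probe sets were called; 10 splits are too few for a share under 0.05.

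The LPS effect at 3 h differed between the genotypes for 47 probe sets, by the direct test of the difference. The genes named there had differences of 2.74 (Atf3), 2.71 (Nr4a1), 2.42 (Egr1), 1.75 (Mt3), 1.60 (Fam107a), 1.57 (Errfi1), 1.28 (Arid5a), 1.22 (Ccn1), 1.03 (Izumo4), 0.99 (Adamts1), -1.44 (Lratd2), -1.25 (Abca5), -1.02 (Orc5), -0.99 (Rsrc1), -0.97 (Dact1), -0.92 (Nars2), -0.90 (Maip1), -0.76 (Acp2), -0.70 (Det1) and -0.64 (Slc49a4). In 11 of 100 splits, the real one included, as many probe sets were called, and the highest other split called 1124, so chance is not excluded for the count and the arrays hold a structure beyond the groups. By gene list, the adjusted p was 3.69e-06 for immediate early genes, 0.000318 for fatty acid oxidation, 0.00601 for MHC class I, 0.0145 for oxidative phosphorylation and 0.0221 for fibroblast markers. At 30 min it was 1.38e-11 for glucocorticoid-responsive genes, 0.00163 for heat shock and chaperones, 0.00533 for STAT3 targets and acute phase genes, 0.00928 for MHC class I, 0.011 for B cells, 0.0214 for monocytes and macrophages, 0.0224 for the circadian clock and 0.0399 for the hypoxia response. Without the second-day arrays the adjusted p at 3 h was 0.277 for fatty acid oxidation, 0.612 for oxidative phosphorylation and 0.0719 for fibroblast markers, but 1.74e-18 for immediate early genes and 0.00128 for MHC class I, and at 30 min the circadian clock (0.122) and B cells (0.0703) lost their call while the other lists kept it. None of these lists passed with an estimated correlation, where the lowest adjusted p was 0.0575, for glucocorticoid-responsive genes. By fry, immediate early genes (adjusted p = 0.0062) and MHC class I (adjusted p = 0.0161) passed at 3 h, and none of the lists passed at 30 min. The MHC class I list was already higher in mutants after PBS (median 0.27), with a genotype median of -0.01 at 3 h after LPS.

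Immediate early genes were higher in mutant than in control hearts 3 h after LPS. Scaling of the arrays is argued against, since the list median was 0.652 after centring and 0.908 after quantile normalization, against 0.762 as deposited. A difference of hybridization day or RNA quality predicts the shift on the second-day arrays, but the first-day mutant array had the highest list median over the control LPS 3 h mean, 1.14, against 0.26 and 0.61 on replicates 1 and 3 and -0.10 to 0.18 on the controls. That array also had the lowest mean correlation with its own group, 0.9535, and high readings of the lung gene Scgb1a1 and the brown fat gene Ucp1. As 1 array excludes nothing about a day, hybridization day or RNA quality stays open. A different response of the mutants to LPS may also account for it, but its test gave an adjusted p of 0.333 with an estimated correlation, so that too stays open, as does a difference in handling between dissection and homogenisation, which was not tested.

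The list of endothelial markers had higher means in mutants after PBS and at 30 min, with 0 of 12 members past the threshold and adjusted p = 0.203 and 0.162 with an estimated correlation. A lower share of heart muscle RNA would raise the markers of every other cell type alike. After PBS the mean change was 0.31 for endothelial and -0.02 for macrophage markers, a difference of 0.334. Its SE of 0.0796 was taken over the genes of the lists, which are not independent replicates, and leaves out the spread between arrays. It therefore cannot decide against a lower share. Fibroblast (0.24), mural (0.16), mesothelial (0.38), platelet (0.61), B cell (0.31) and neutrophil (0.21) means were also above 0, so a lower share stays open after PBS. At 30 min endothelial and macrophage means were 0.26 and 0.13, a difference of 0.126 (SE 0.0826, also over genes), which a lower share could give. More RNA from vessel wall cells also stays open. The mean of 24 endothelial and mural markers was 0.25 higher in mutants over these conditions, where the pattern was found. At 3 h after LPS the difference was 0.0384 (SE 0.125, over arrays) with overlapping arrays. Whether cell number or expression per cell differed was not tested.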

How the results depend on the processing

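Fits without the 2 second-day arrays or within single days were chosen after seeing the data; all other alternatives were planned. The Kcnj8 level, mutant against control, kept its direction and its call under all alternatives run, at -3.85 to -3.75 without single arrays. No called list and none of the 147 single-gene results tried reversed, while Pecam1, a list member outside these, went from -1.56 to 0.08 in mutants 3 h after LPS without the second-day arrays, some lists without a call changed sign, and the direction with more calls turned for several counts. Without the second-day arrays, risen and fallen probe sets were 697 and 784 for LPS 3 h in controls, 1230 and 666 for the genotype at 3 h and 748 and 427 for LPS 30 min in controls. Of the 147 single-gene results 19 weakened without the second-day arrays, 73 with day as a block and 71 with only the arrays compared, and 55 of the 83 tested with first-day arrays only, and 27 list calls were lost without the second-day arrays. The 114 list calls became 13 with an estimated correlation and 61 with fry, and both counts include genotype calls of the K-ATP list, which holds Kcnj8 itself. The cause of the changes below was not tested. Fits with fewer arrays have fewer degrees of freedom, which does not account for counts that rose with only the arrays compared. Those were comparisons among PBS and LPS 30 min arrays, which then no longer share a spread with the LPS 3 h arrays. Array weights were 0.115 to 0.294 on mutant LPS 3 h arrays, against 0.965 to 2.76 on PBS and LPS 30 min arrays.

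Counts of called probe sets that moved by over 1.5 times follow, for LPS effect at 3 h in control hearts, LPS effect at 3 h in mutant hearts and genotype difference in the LPS effect at 3 h (LPS 3 h), mutant against control after PBS, mutant against control 3 h after LPS, mutant against control 30 min after LPS and mutant against control over the 3 conditions (genotype), LPS 30 min against PBS 3 h in control hearts, the same in mutants and genotype difference in the LPS 30 min effect (LPS 30 min), and LPS 3 h against LPS 30 min, in this order. Array weights gave 2469 for LPS 3 h in controls, 5949 for the difference at 3 h, 736, 1156 and 6452 for the genotype after PBS, at 30 min and over all, and 4221, 2627 and 13 for LPS 30 min in controls, in mutants and their difference. In the mutant LPS 3 h group these weights favoured the second-day arrays over replicate 2. The 3' minus 5' covariate gave 641, 3731 and 190 for LPS 3 h, 24, 1014, 18 and 544 for the genotype, and 1106 and 794 for LPS 30 min. Only the arrays of the groups compared gave 6, 66 and 1 for LPS 3 h, 327, 1 and 675 for the genotype after PBS, at 3 h and at 30 min, 3610, 806 and 2 for LPS 30 min, and 4658 for 3 h against 30 min. Day as a block gave 691, 2107 and 104 for LPS 3 h, 48, 609, 46 and 611 for the genotype, 1 and 0 for LPS 30 min, and 10 for 3 h against 30 min. A log2 change of at least 1 left 100, 2040 and 24 for LPS 3 h, 1673, 2 and 20 for the genotype at 3 h, at 30 min and over all, 30 and 14 for LPS 30 min, and 497 for 3 h against 30 min. Without the second-day arrays there were 1481, 4880 and 535 for LPS 3 h, 95, 1896 and 127 for the genotype in the 3 conditions, and 1175 and 581 for LPS 30 min. Of the original calls, 225 of 225, 2371 of 9522 and 38 of 47 for LPS 3 h were among those, and 843 of 8309 for the genotype at 3 h. The first day alone gave 1816 for LPS 3 h in mutants and 9 and 423 for the genotype after PBS and at 3 h, and the third day alone 675 at 30 min. The trend with a robust prior gave 14 for the difference at 3 h and 1 for the genotype at 30 min, quantile normalization 42 and 6 for LPS 30 min in controls and mutants, and the median-level filter 7 for the genotype at 30 min.

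Leaving out single arrays, in fits that pool the spread over the groups, gave 33 to 611 for LPS effect at 3 h in control hearts, 3222 to 14773 for LPS effect at 3 h in mutant hearts and 8 to 10621 for genotype difference in the LPS effect at 3 h. It gave 1 to 4 for mutant against control after PBS, 1688 to 14775 for mutant against control 3 h after LPS, 1 to 2 for mutant against control 30 min after LPS and 415 to 8904 for mutant against control over the 3 conditions. It gave 3 to 12 for LPS 30 min against PBS 3 h in control hearts, 0 to 20 in mutants, 0 to 0 for their difference, and 6855 to 15988 for LPS 3 h against LPS 30 min. The counts of 14773, 10621, 14775 and 8904 came without mutant LPS 3 h replicate 2, which leaves only the second-day arrays in that group.

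The replicate numbers did not pair the arrays. Same-numbered arrays' deviations from their group means correlated at -0.31 to 0.39 (median 0.02, against 0.005 for other numbers), 12 of 45 pairs were above 0.1, and 8 of 18 arrays lay closest to their own number. With the number as a replicate block the count was 21 for the difference at 3 h, 1 for the genotype at 30 min and 41 for LPS 30 min in controls, and no other count moved by over 1.5 times. The sex covariate was not run, as the arrays did not differ in it. The signal floor limits differences of dim probe sets, among them Kcnj8 in mutants.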

Other observations

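The neighbour test of Kcnj8 and the counts over other splits were fixed before their results were seen. The neighbour test used the fit without the second-day arrays, however, which was chosen after seeing the data. The remaining values here were looked at after the other results.

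Some genes outside the inflammatory groups marked single arrays or 1 condition. The brown fat gene Ucp1, chosen after its values were seen, read 8.43 and 8.69 on control LPS 30 min replicates 2 and 3 and 9.13 on mutant LPS 3 h replicate 2, against 4.62 to 7.62 on the other 15 arrays. In control hearts 30 min after LPS the adipocyte list had 0 of 8 members past the threshold and 3 higher adjusted over the list alone, with Adipoq at 2.13 (limma adjusted p = 0.179; camera adjusted p = 0.000231, but adjusted p = 0.0775 with an estimated correlation). Of the lung genes, Sftpc, a surfactant gene of alveoli and chosen after its values were seen, read 5.18 and 5.31 on mutant LPS 3 h replicates 2 and 3, where Scgb1a1 was at 9.90 and 8.80, and 4.53 to 5.39 on the other arrays. The platelet gene Ppbp read 8.62 and 8.65 on mutant PBS replicates 1 and 3 and 6.27 on replicate 2.

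Mesothelial markers, from the heart's outer lining, had a median of -0.54 in mutants 30 min after LPS against PBS, with 0 of 8 past the threshold and 4 lower adjusted over the list alone (camera adjusted p = 0.000482, but adjusted p = 0.491 with an estimated correlation). They were also lower against PBS in controls at 30 min (median -0.31, adjusted p = 0.0466, but adjusted p = 0.925 with an estimated correlation), in controls at 3 h (-0.35, adjusted p = 0.0189, but adjusted p = 0.448 with an estimated correlation) and in mutants at 3 h (-0.55, adjusted p = 0.0372, but adjusted p = 0.502 with an estimated correlation). Within each genotype these comparisons share the 3 PBS arrays, which the genotype comparison after PBS uses again, so they are not independent of each other. After PBS they were higher in mutants than in controls (median 0.36, adjusted p = 0.00327, but adjusted p = 0.356 with an estimated correlation), with 1 of 8 higher adjusted over the list alone and Krt19 at 0.73.

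It was asked whether genes next to Kcnj8 on its chromosome, carried along with the mutation from another strain, could account for genotype differences. Calls were taken from the genotype effect over the conditions in the fit without the second-day arrays. Among the 100 measured genes nearest to Kcnj8, 2 passed there, Apold1 (1.04) and Itpr2 (0.34), against a median of 4 and a 95th percentile of 8 over 18133 such windows, of which 93.4% held as many. An excess near Kcnj8 is therefore argued against in that fit.

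Other splits of the same arrays were counted for the remaining comparisons. For the genotype averaged over the conditions 1 of 100 splits, the real one with 1055 calls, reached that count, and the highest other called 32. Chance is thus argued against, as far as 100 splits can show. The real split has both second-day arrays on the mutant side, so the count does not separate genotype from day or RNA quality. For LPS 3 h against 30 min 1 of 100, the real one, reached 11020, and the highest other called 8547, so chance is argued against for the count while the arrays hold other structure. No day held arrays of both times, so this count does not separate time from hybridization day. For the genotype difference in the 30 min effect, all 100 splits called at least the real 0, by limma, with 881 probe sets at an unadjusted p under 0.05. Where 3 arrays stand against 3 the 10 splits are too few for a share under 0.05. There the real and highest other counts were 225 and 0 for LPS 3 h in controls, 4 and 0 for the genotype after PBS and again at 30 min, and 64 and 0 and 22 and 0 for LPS 30 min in controls and mutants. For LPS 3 h in mutants they were 9522 and 4112, the latter with mutant PBS replicate 1 grouped with the 2 second-day arrays.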
